A study of Mus musculus with 12 samples.

How the data were processed

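RNA was extracted from 12 cultures of EO771-tdT-LM2 mouse breast cancer cells with a Quick-RNA kit and sequenced on Illumina libraries, per the labels' protocols. The cells were placed in glucose-deprived medium for 30 minutes, seeded in plates of 12 wells and treated for 24 hours. The deposited table holds raw counts per gene, not scaled, for 55414 gene IDs and the 12 libraries; the values are whole numbers. The submitters' processing notes name kallisto 0.46.2, FastQC and MultiQC, and the genome builds GRCm39 and mm10, without saying which build the counts rest on, so no coordinates are given. How reads that match several genes were counted, and whether strand was used, is not stated there. A symbol was matched to 52081 IDs, and 3333 IDs had none and held 6.55% of all counts, nearly all of it (6.47%) on 1 feature. Total counts were 5616398 to 8093754 per library, so that 3 counts correspond to 0.371 to 0.534 CPM.

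Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15, on the groups), which left 11332. Counts were scaled by TMM and fitted in 1 model with 4 groups of 3 libraries by edgeR 4.0.16 with the quasi-likelihood F test under R 4.3.3, with no covariate. There were 7 comparisons, including the interaction of GDNF and antibody. P-values were adjusted by Benjamini-Hochberg within each comparison and called at 0.05. Tests were 2-sided. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run on the same genes, DESeq2 with its independent filtering, which in GDNF against control adjusted over 1885 of them. Normalised CPM use the TMM library sizes.

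A total of 36 gene lists were fixed for the pathways, complexes and cell types that fit these cells and treatments, and 32 had at least 5 tested members. The lists of basal and myoepithelial (4 tested members), leukocyte, endothelial, and neuron and glia markers (3 each) were too small to test. Lists were tested with camera (preset correlation 0.01) on limma-voom values, adjusted over the 32 lists, and again with an estimated correlation and with fry, whose directional p tests whether a list's genes move one way. A list's level in a library is the mean over its tested members of log2 CPM (pseudocount 2) minus the control mean. Members were also adjusted over the list alone. Medians of lists are of edgeR log2 fold changes unless limma-voom values are named; under the alternatives and without single libraries they are of limma-voom values.

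The genes named are, by rule, up to 10 passing genes in each direction with separated groups, up to 4 members with the smallest p of each called list, the genes Ncam1, Gfra1, Ret, Gdnf and Fyn, and, where no gene passed, the 3 with the smallest p in each direction. Predicted genes with no proper symbol were counted but not named. Genes outside this rule were chosen after their values were seen and are the most abundant feature, Lars2 and the genes named for alternatives with 5 calls or fewer. The comparisons, tests, lists, naming rule and first set of alternatives were chosen before the data were examined.

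Agreement of an effect between arms was the correlation across genes of its log2 fold changes in the 2 arms, with the labels permuted within arms (400 relabellings). GC content and transcript length were taken from the reference for 11313 of the tested genes (99.8%), and each library's trend on them was fitted by lowess (span 0.3). Whether replicate numbers pair libraries was checked from the correlation of same-numbered libraries' deviations from their group means.

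The alternatives chosen beforehand were DESeq2, limma-voom, DESeq2 size factors, upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, fits on the compared groups alone, the replicate number as a block, robust estimation, an added 1.5-fold threshold, effects averaged over arms, and leaving out each library. Added after seeing the data were removal of the GC content and transcript length trend, that removal without GDNF replicate 3, the data without the 4 libraries with a falling GC trend, limma-voom with sample quality weights, DESeq2 without independent filtering, and a filter of 5 CPM in 3 libraries. The test was first tested on simulated counts with 200 of 11332 genes changed. With no gene changed it called 0 for GDNF against control and 2 for the antibody against control. A list shifted in the simulation of GDNF against control was recovered by camera with either correlation and by fry, with 0 other lists called. The simulated genes varied independently, so this does not test for list calls that arise where genes vary together. No sample was left out of the comparisons.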

Results

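The data are RNA-seq counts per gene from 12 cultures of EO771-tdT-LM2, a mouse breast cancer cell line that carries the tdTomato label. The cells were kept in glucose-deprived medium (10 mg/dl glucose and 1% FBS) and treated for 24 hours. In 3 control cultures they received 0.1% BSA with 2.5 µg/mL IgG. In 3 cultures they received 0.2 µg/mL GDNF, a neurotrophic growth factor, with the IgG. In 3 cultures they received 2.5 µg/mL of an antibody against NCAM1, a cell adhesion molecule that can act as a GDNF receptor, with BSA. The last 3 cultures received both GDNF and the antibody. Total counts ran from 5616398 to 8093754 per library, and 11332 genes had enough counts to be tested. The labels call the cultures of a group triplicates and do not say whether they were separate experiments. P-values of single genes thus measure only the spread between these cultures. Those of camera at the preset correlation of 0.01 set a list's genes against the other genes, so they do not directly measure that spread.

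Transcripts encoded in the mitochondrial genome made up 10.2% of the counts in GDNF replicate 3 and 4.11 to 5.29% in the other 11 libraries. The most abundant feature of the table, a gene ID with no symbol (ENSMUSG00000119584, picked out after its values were seen), held 0.543% of the counts in GDNF replicate 3 and 3.79 to 9.85% elsewhere. What this feature encodes was not settled here, so its share is not read as expression. Lars2, picked out in the same way, held 0.0372% in GDNF replicate 3 and 0.236 to 0.793% elsewhere. The next lowest share of both was in anti-NCAM1 replicate 2, at 3.79% for the feature and 0.236% for Lars2. In control replicate 1 the shares were 9.36% and 0.793%. As the share of Lars2 varied with that of the feature, it is not read as expression either. Rank correlations across genes were 0.974 to 0.984 between GDNF replicate 3 and the other libraries, and at least 0.991 among those. Each gene's deviation from its mean over the 12 libraries was fitted on GC content and transcript length. The slope on GC content, in log2 units per 10 points, was -0.34 in GDNF replicate 3 and -0.16 in GDNF replicate 2. It was -0.08 in anti-NCAM1 replicate 1, -0.09 in anti-NCAM1 replicate 3 and 0.05 to 0.12 in the other 8 libraries. These slopes are relative to the mean of the 12 libraries, GDNF replicate 3 included. A slope below or above 0 is thus not an absolute trend. The 4 libraries with a slope below 0, called falling, lie in the groups given GDNF alone or the antibody alone. Without them each of those groups holds 1 library. That refit thus has no spread within those groups, and its medians and counts of genes decide nothing about a cause.

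**Figure D1:**
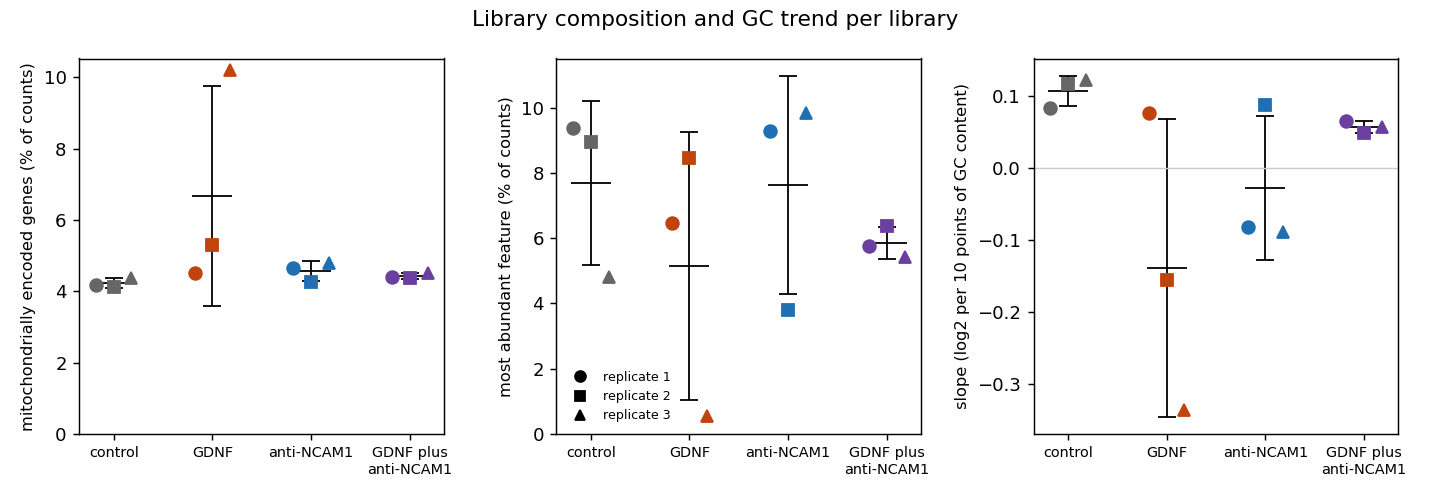
Each point is 1 of 12 libraries, with its replicate number shown by its shape; lines and bars give the mean and SD of the 3 libraries of each group. The panels plot the percent of counts on mitochondrially encoded genes, the percent on the most abundant feature, and the slope of expression on GC content; GDNF replicate 3 stands at 10.2%, 0.543% and -0.34.

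Ncam1, the antibody's target, was expressed at 9.19 ± 2.39 CPM in control, scaled for library size, 8.74 ± 2.04 with GDNF, 8.89 ± 0.992 with the antibody and 8.63 ± 0.875 with both (SD, n = 3 each). Fyn, a kinase downstream of NCAM1, stood at 80.3 ± 4.15 in control and 81.8 ± 8.29 with GDNF (SD, n = 3). Gdnf itself was expressed by the cells, at 13.95 ± 1.63 CPM in control, 11.2 ± 0.897 with GDNF, 10.6 ± 0.695 with the antibody and 12.5 ± 1.10 with both (SD, n = 3). The Gdnf difference from control was -0.32 on the log2 scale (SE 0.14, edgeR adjusted p = 0.236) with GDNF and -0.39 (SE 0.15, adjusted p = 0.853) with the antibody, and neither passed. Transcripts of Gfra1 and Ret were near the limit of detection. Gfra1, the high-affinity co-receptor, had 0 to 4 counts per library and 0.182 CPM over all 12 (95% Poisson interval 0.102 to 0.30). Ret, the receptor tyrosine kinase, had 0 to 2 counts per library and 0.0850 CPM (0.0342 to 0.175). Neither was tested. These intervals cover counting error only. Of the 23 genes fixed as GDNF receptors and ligands, 12 could be tested, and camera called the group in no comparison (adjusted p = 0.299 for GDNF against control).

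**Figure D2:**
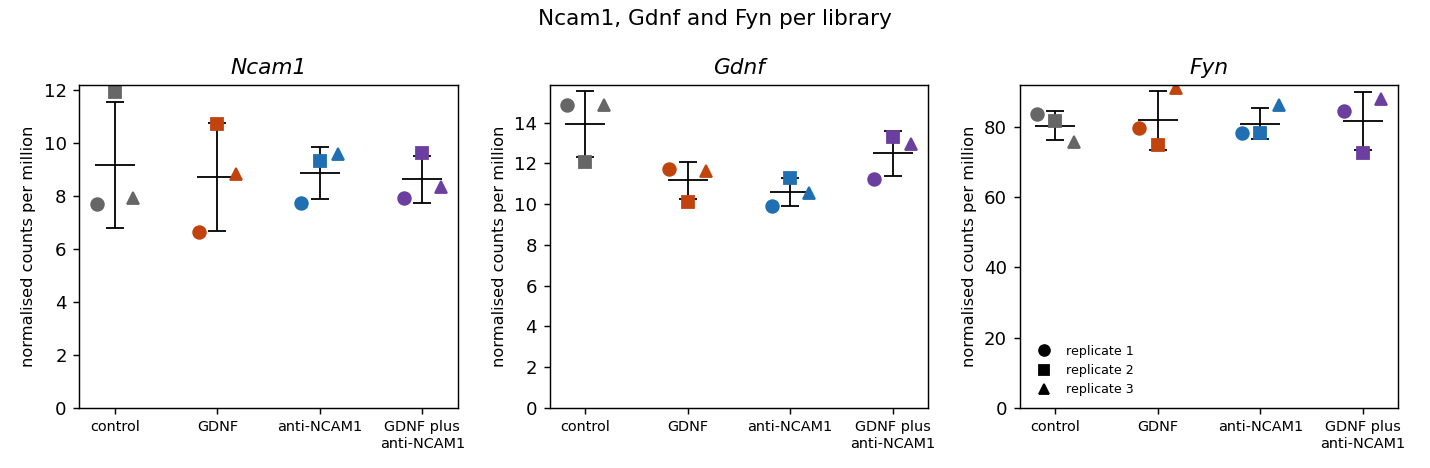
Normalised CPM of Ncam1, Gdnf and Fyn in each of the 12 libraries, with the mean and SD of the 3 libraries of each group. Ncam1 group means lie between 8.63 and 9.19 CPM, within the spread of the replicates.

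The first comparison asks what GDNF did to glucose-deprived cells. Mitochondrially encoded genes, which code for subunits of the respiratory chain and its ribosome, were the group farthest above control: 11 of 12 measured members were higher, with a median log2 fold change of 0.74 (camera adjusted p = 0.000232, n = 3 against 3). This call, like those of the 6 groups that follow, was lost when the correlation between genes was estimated (adjusted p = 0.483 with an estimated correlation, 0.492 for the ribosomal proteins). mt-Nd2 was 0.95 higher (SE 0.26) and mt-Cytb 0.74 (SE 0.19). The group's mean level above control was 1.15 in GDNF replicate 3, 0.39 in replicate 2 and 0.08 in replicate 1. Mitosis genes were above control in 25 of 32 members (median 0.17), led by Hmmr at 0.50 (SE 0.15) and Cenpe at 0.39 (SE 0.13), and their level was 0.29, 0.10 and 0.01 in GDNF replicates 3, 2 and 1. Glycolysis and glucose uptake genes were below control in 21 of 23 members (median -0.11), among them the glucose transporters Slc2a1 at -0.24 (SE 0.09) and Slc2a3 at -0.38 (SE 0.13) and the lactate exporter Slc16a3 at -0.48 (SE 0.20). Their level was -0.38, -0.12 and 0.03 in replicates 3, 2 and 1, and without the 4 libraries with a falling GC slope the median turned to 0.0075.

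Axon guidance genes were lower with GDNF in 17 of 18 members (median -0.21), with the guidance ligand Ntn1 at -0.38 (SE 0.13) and its receptor Unc5b at -0.33 (SE 0.12). Their level was -0.43, -0.31 and 0.02 in GDNF replicates 3, 2 and 1. Antigen presentation genes were lower in 10 of 12 (median -0.26), with the immunoproteasome subunit Psmb8 at -0.44 (SE 0.14) and the peptide transporter Tap2 at -0.55 (SE 0.19), while B2m, the light chain of MHC class I, was higher at 0.47 (SE 0.15). Their level was -0.47, -0.20 and 0.02 in the same order, and without the 4 libraries with a falling GC slope the median turned to 0.030. Matrix genes were lower in 16 of 22 (median -0.16), with Col1a1 at -0.35 (SE 0.09), and their level was -0.19, -0.14 and -0.04; with the trend on GC content and transcript length removed the median turned to 0.025. Fibroblast markers, 5 of 12 of them tested and Col1a1 among them, stood at -0.11, -0.17 and -0.07 in the same order and were not called (median -0.17, adjusted p = 0.290). Ribosomal protein genes were higher in 45 of 75 (median 0.06), with Rpl35 at 0.46 (SE 0.12). In GDNF replicate 3 their level was -0.08, against 0.12 and 0.09 in replicates 2 and 1. Rpl36a, which is not among the 75, stood at 0.43 (SE 0.09). Counts on ribosomal protein, mitochondrial and MHC class I genes are uncertain where near-identical copies or pseudogenes share reads.

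No single gene passed in edgeR for GDNF against control (0 of 11332, smallest adjusted p = 0.165), and 2303 had an unadjusted p under 0.05. By chance 566.6 would on average in each comparison, but where genes vary together the number can lie far from that. The antibody against control had 599. GDNF plus anti-NCAM1 had 284 against the antibody and 221 against control. The 2303 alone thus do not show a response to GDNF. Among the genes with the smallest p, none of which passed, were Rpl36a, Xlr at 0.70 (SE 0.15), Zbtb40 at -0.57 (SE 0.11), Irf2bp1 at -0.66 (SE 0.15) and Parp10 at -0.74 (SE 0.17). DESeq2, whose independent filtering adjusted over only 1885 genes here, passed 31, 26 higher and 5 lower, with 1960 at an unadjusted p under 0.05. Adjusted over all 11332 it passed 0 (smallest adjusted p = 0.0784). The 31 include Rpl36a (DESeq2 adjusted p = 0.0222), Rpl35, Rpl5, Rpl7, Rps24 and Col1a1 (0.0491 each). limma-voom passed 0, with 2448 unadjusted. In edgeR 736 passed with no filter and 1 with the trend on GC content and transcript length removed and GDNF replicate 3 left out. With sample quality weights limma-voom passed 2614. Members past the threshold adjusted over the list alone numbered 9 of 12 for the mitochondrial genes, 10 of 75 for the ribosomal proteins, all higher, 3 of 12 for antigen presentation (1 higher, 2 lower), 1 of 22 for matrix and 0 for the other 3 groups, and over all genes tested the count was 0 in each. Camera called these 7 of 32 groups (adjusted p = 0.000232 to 0.0297). Without GDNF replicate 3 the mitosis, glycolysis and antigen presentation calls ended (adjusted p = 0.0890, 0.102 and 0.229) and 4 groups were called. Without GDNF replicate 1, 2714 genes passed in edgeR and the ribosomal call ended (adjusted p = 0.200). The GDNF group then held only replicates 2 and 3, with GC slopes of -0.16 and -0.34, so these genes cannot be told from that trend. The ribosomal call also ended without GDNF replicate 2 (0.269) and control replicate 1 (0.0756), the matrix call without GDNF replicate 2 (0.0967) and control replicates 1 and 3 (0.0503 and 0.0842), and the antigen presentation call without control replicate 3 (0.0727).

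Medians of the 7 groups for GDNF against control in limma-voom values moved by over 1.5 times without single libraries. With GDNF replicate 3 left out, the mitochondrial genes went from 0.65 to 0.28, mitosis from 0.16 to 0.049, glycolysis from -0.12 to -0.050, antigen presentation from -0.29 to -0.10, axon guidance from -0.22 to -0.13, matrix genes from -0.17 to -0.077 and ribosomal proteins from 0.050 to 0.10. With GDNF replicate 1 left out, glycolysis stood at -0.20, antigen presentation at -0.47 and axon guidance at -0.33. Without GDNF replicate 2, ribosomal proteins stood at 0.030. Removal of the trend on GC content and transcript length kept the calls of mitochondrial (0.35, adjusted p = 0.0322), mitosis (0.091, 0.0186) and antigen presentation genes (-0.15, 0.0322). It ended those of glycolysis (-0.048, 0.0922), ribosomal (0.047, 0.0922), axon guidance (-0.025, 0.867) and matrix genes (0.025, 0.867). With GDNF replicate 3 left out as well, ribosomal proteins were called (0.067, 2.54e-12) and the other 6 groups were not. Medians of these 6 were 0.064 for mitochondrial, 0.031 for mitosis and 0.00010 for glycolysis genes. For antigen presentation, axon guidance and matrix genes they were -0.047, -0.020 and -0.029.

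**Figure D3:**
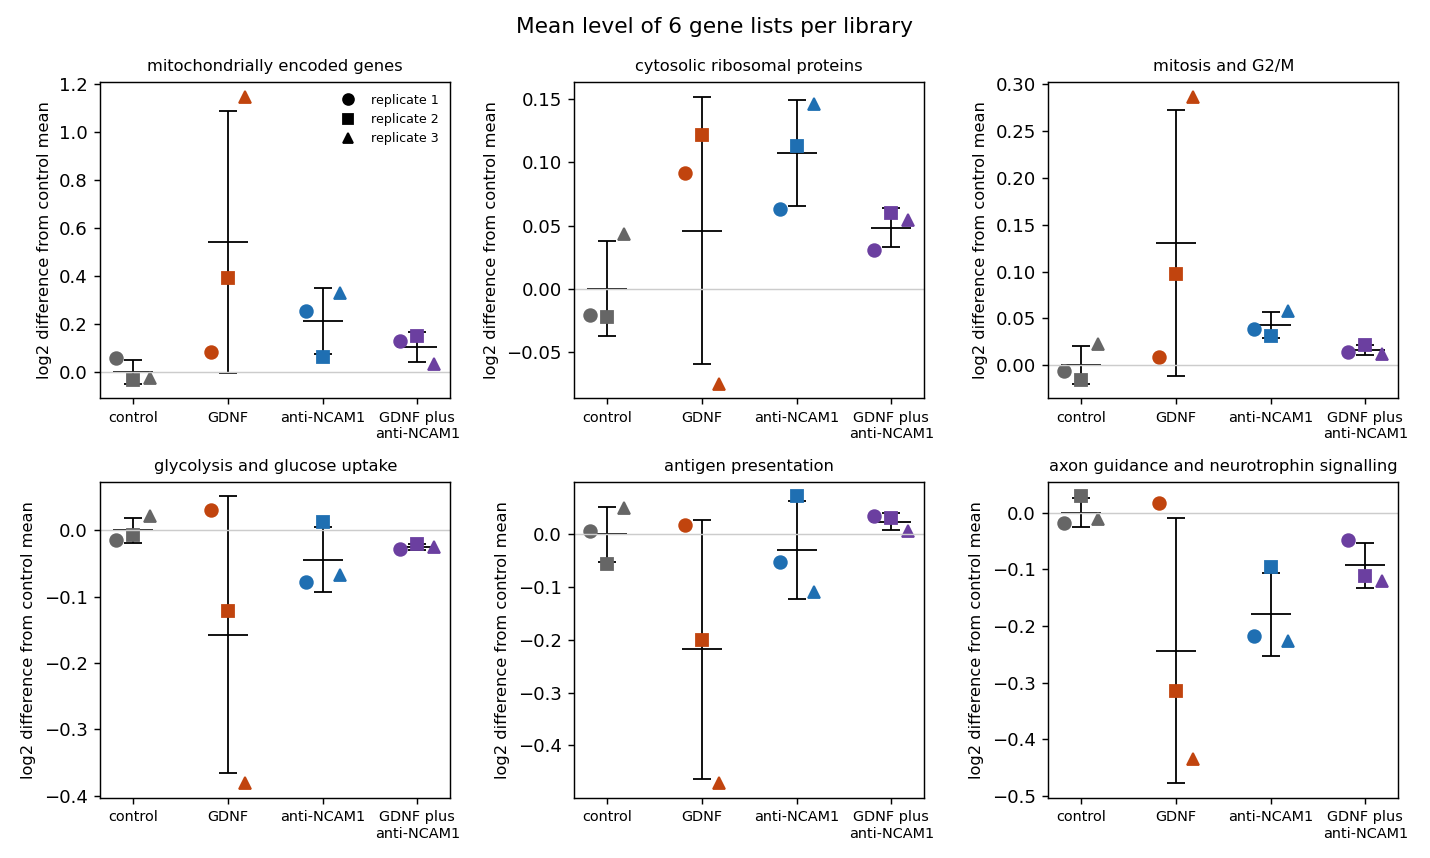
Mean log2 level of 6 gene groups in each of the 12 libraries relative to the control mean, with the mean and SD of the 3 libraries of each group. For mitochondrially encoded genes, GDNF replicate 3 stands at 1.15, GDNF replicate 2 at 0.39 and GDNF replicate 1 at 0.08, beside the control libraries at -0.03 to 0.06.

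The second comparison asks what the antibody did without added GDNF. Ribosomal protein genes were above control in 66 of 75 members with the antibody (median 0.12, camera adjusted p = 1.15e-12, n = 3 against 3), with Rpl11 at 0.23 (SE 0.06) and Rpl35a at 0.22 (SE 0.07). This call, like those of the 5 groups that follow, was lost when the correlation between genes was estimated (adjusted p = 0.308 with an estimated correlation for ribosomal proteins, 0.240 for ERK targets and 0.459 for the other 4). Their level above control was 0.06, 0.11 and 0.15 in anti-NCAM1 replicates 1, 2 and 3. Axon guidance genes were below control in 18 of 18 members (median -0.15), with the semaphorin receptor Plxna1 at -0.28 (SE 0.09) and the ephrin receptor Epha2 at -0.24 (SE 0.10). Genes induced by ERK signalling were below control in 25 of 29 (median -0.11), with Jun at -0.20 (SE 0.09), Fosb at -0.65 (SE 0.32) and the growth factor feedback gene Dusp5 at -0.21 (SE 0.12). Anti-NCAM1 replicates 1 and 3, with the falling GC slopes, stood at -0.22 and -0.23 for axon guidance and -0.15 and -0.15 for ERK targets. Replicate 2 stood at -0.09 and -0.05.

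Nuclear genes of oxidative phosphorylation were higher with the antibody in 38 of 55 members (median 0.05), with Ndufb5 at 0.25 (SE 0.09). Fatty acid synthesis genes were lower in 15 of 18 (median -0.05), with fatty acid synthase, Fasn, at -0.29 (SE 0.12). Of 23 epithelial markers, 16 had under 3 counts per library on average, and the group rests on the 7 tested. These were higher in 6 of 7 (median 0.32), with Epcam at 0.32 (SE 0.13) and Erbb3 at 0.35 (SE 0.22). For oxidative phosphorylation, anti-NCAM1 replicates 1, 2 and 3 stood at -0.03, 0.08 and 0.08. For fatty acid synthesis they stood at -0.10, -0.03 and -0.09. The epithelial group stood at 0.30, 0.23 and 0.19. Its mean level was also above control with GDNF alone, at 0.17 ± 0.26, and with both agents, at 0.26 ± 0.033 (SD, n = 3 each).

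No gene passed for the antibody against control in edgeR (0 of 11332, smallest adjusted p = 0.853, 599 at an unadjusted p under 0.05), in DESeq2 (0, with 440 unadjusted) or in limma-voom (0, with 605). In edgeR 33 passed with only the compared groups fitted and 8 with no filter. With the trend on GC content and transcript length removed and GDNF replicate 3 left out, 18 passed. With sample quality weights limma-voom passed 277. Among the genes with the smallest p, which did not pass, were Retreg1 at 0.53 (SE 0.13), Magef1 at 0.70 (SE 0.19), Sipa1l3 at -0.36 (SE 0.08), Crocc at -0.45 (SE 0.12) and Ubr4 at -0.26 (SE 0.07). In the 6 groups called by camera (adjusted p = 1.15e-12 to 0.0477), 0 members passed when adjusted over the list alone and 0 over all genes. Without GDNF replicate 3, 8 genes passed in edgeR, 1 higher and 7 lower, Rpl36a, Sipa1l3 and Ubr4 among them. The ribosomal, axon guidance and ERK calls held without each of the 12 libraries in turn, but removal of the trend ended the calls of axon guidance (-0.055, adjusted p = 0.192) and ERK targets (-0.058, 0.163). It also ended those of fatty acid synthesis (-0.058, 0.192) and oxidative phosphorylation (0.00072, 0.80), and kept those of ribosomal proteins (0.065, 6.66e-08) and epithelial markers (0.34, 0.000917). When GDNF replicate 3 was left out too, those 2 and ERK targets (-0.058, 0.0421) were called, and the oxidative phosphorylation median was -0.00048. The epithelial call ended without control replicate 1 or 2, anti-NCAM1 replicate 1 or 2, GDNF plus anti-NCAM1 replicate 1 or 2, or GDNF replicate 3 (adjusted p = 0.0524 to 0.128). The fatty acid call ended without control replicate 1 or 3, anti-NCAM1 replicate 1 or 3, or GDNF plus anti-NCAM1 replicate 1 or 2 (0.0524 to 0.124). The oxidative phosphorylation call ended without control replicate 1 or 2, anti-NCAM1 replicate 2 or 3, or GDNF plus anti-NCAM1 replicate 1 or 2 (0.0524 to 0.267). The number of groups called was 3 without control replicate 1 or GDNF plus anti-NCAM1 replicate 1 or 2, and 11 without GDNF replicate 1. With the replicate number as a block it was 10. Medians in limma-voom values moved by over 1.5 times without anti-NCAM1 replicate 3 for ERK targets (from -0.11 to -0.065) and oxidative phosphorylation (from 0.055 to 0.029), without control replicate 3 for oxidative phosphorylation (to 0.082), and without control replicate 2 for fatty acid synthesis (from -0.048 to -0.087).

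The third comparison asks what the antibody did to cells given GDNF. Mitochondrially encoded genes were lower in 11 of 12 members with GDNF plus anti-NCAM1 than with GDNF alone (median -0.70, camera adjusted p = 0.000798, n = 3 against 3), with mt-Nd2 at -0.92 (SE 0.26) and mt-Cytb at -0.70 (SE 0.19). This call, like those of the 4 groups that follow, was lost when the correlation between genes was estimated (adjusted p = 0.633 with an estimated correlation for each). Their level above control was 0.13, 0.15 and 0.03 in the 3 libraries given both agents, and 0.08, 0.39 and 1.15 in those given GDNF. Mitosis genes were lower in 24 of 32 (median -0.15), with Tpx2 at -0.36 (SE 0.11) and Prc1 at -0.32 (SE 0.10). Glycolysis genes were higher in 17 of 23 (median 0.11), with Slc2a1 at 0.25 (SE 0.09) and Slc16a3 at 0.43 (SE 0.20). Antigen presentation genes were higher in 10 of 12 (median 0.25), with Tap2 at 0.50 (SE 0.20) and H2-D1 at 0.28 (SE 0.11), while B2m was at -0.46 (SE 0.15). Axon guidance genes were higher in 15 of 18 (median 0.15), with Sema3b at 0.35 (SE 0.11) and Unc5b at 0.30 (SE 0.12). The axon guidance median turned to -0.020 with the trend on GC content and transcript length removed, to -0.031 with GDNF replicate 3 left out as well, and to -0.094 without the 4 libraries with a falling GC slope. The glycolysis median turned to -0.0021 and -0.030 in the latter 2 settings, and without the 4 libraries the mitosis and antigen presentation medians turned to 0.011 and -0.024. Within the GDNF group, replicate 3 stood farthest from control in each of these 5 groups.

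In edgeR 0 genes passed for GDNF plus anti-NCAM1 against GDNF (smallest adjusted p = 0.331, 1582 at an unadjusted p under 0.05), in DESeq2 0 (1350 unadjusted) and in limma-voom 0 (1616). In edgeR 348 passed with no filter and 1 with the trend on GC content and transcript length removed and GDNF replicate 3 left out. With sample quality weights limma-voom passed 1462. The genes with the smallest p did not pass. They were Mfsd3 at 1.23 (SE 0.27), the inositol transporter Slc5a3 at 0.39 (SE 0.09), the DNA polymerase Poll at 0.70 (SE 0.16), Nucb2 at -0.70 (SE 0.16), Gtf3c6 at -0.68 (SE 0.16) and Cox20 at -1.62 (SE 0.38). Adjusted over the list alone, 6 of 12 mitochondrial genes passed, all lower, and 0 members of the other 4 groups, against 0 over all genes. The 5 camera calls had adjusted p = 0.000798 to 0.0211. Without GDNF replicate 3 the mitosis, antigen presentation and axon guidance calls ended (adjusted p = 0.307 each), as did that for glycolysis (0.432), and 2 groups were called. Without GDNF replicate 2 the antigen presentation (0.0583) and axon guidance (0.110) calls ended and 3 groups were called, and the axon guidance call also ended without GDNF plus anti-NCAM1 replicate 1 (0.0630). Without GDNF replicate 1, which leaves only GDNF replicates 2 and 3 with their falling GC slopes, 1990 genes passed in edgeR.

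Medians of the 5 groups for GDNF plus anti-NCAM1 against GDNF in limma-voom values moved by over 1.5 times without either of a pair of libraries. When GDNF replicate 3 was omitted, the mitochondrial genes went from -0.55 to -0.17, mitosis from -0.14 to -0.046, glycolysis from 0.12 to 0.019, antigen presentation from 0.28 to 0.12 and axon guidance from 0.17 to 0.070. When GDNF replicate 1 was omitted they stood at -0.85, -0.22, 0.22, 0.43 and 0.27, in the same order. Removal of the trend on GC content and transcript length kept the calls of mitochondrial (-0.37, adjusted p = 0.0334), mitosis (-0.083, 0.0280) and antigen presentation genes (0.18, 0.0334) and ended those of glycolysis (0.042, 0.322) and axon guidance (-0.020, 0.587). With GDNF replicate 3 left out as well, mitochondrial genes stayed called (-0.069, 0.00220) and the other 4 did not.

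The fourth comparison asks what GDNF did in cells given the antibody. Ribosomal protein genes were lower in 59 of 75 members with both agents than with the antibody alone (median -0.07, camera adjusted p = 1.10e-06, n = 3 against 3), with Rpl30 at -0.20 (SE 0.08). The call was lost when the correlation between genes was estimated (adjusted p = 0.719 with an estimated correlation). The level above control was 0.03 to 0.06 in the libraries given both and 0.06 to 0.15 in those given the antibody. No other group was called. The single genes with the smallest p, which did not pass, were Crocc at 0.55 (SE 0.12), Sipa1l3 at 0.36 (SE 0.09), the keratin Krt16 at 1.85 (SE 0.46), Sfmbt1 at -0.44 (SE 0.11), Ppp1r3e at -0.59 (SE 0.17) and Mmd at -0.52 (SE 0.15). In edgeR 0 genes passed (smallest adjusted p = 0.999, 284 at an unadjusted p under 0.05), in DESeq2 0 (173) and in limma-voom 0 (256). In edgeR 5 passed with only the compared groups fitted and 4 with no filter, and limma-voom with sample quality weights passed 7. Adjusted over the list alone, 0 of 75 ribosomal protein genes passed, and 0 over all genes. The call held without each of the 12 libraries, with the median in limma-voom values going from -0.067 to -0.036 without anti-NCAM1 replicate 3 and to -0.040 after removal of the trend (adjusted p = 0.000199), but the number of groups called was 7 without GDNF replicate 3 and 2 without GDNF replicate 1, anti-NCAM1 replicate 2 or GDNF plus anti-NCAM1 replicate 1.

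The interaction asks whether the effect of GDNF differed between cells with and without the antibody, and a positive value is a GDNF effect that was higher with the antibody than without it. Mitochondrially encoded genes had the lowest values, below 0 in 11 of 12 members (median -0.84, camera adjusted p = 0.000654, n = 3 in each of 4 groups), with mt-Nd2 at -1.09 (SE 0.36). This call, like those of the 8 groups that follow, was lost when the correlation between genes was estimated (adjusted p = 0.507 with an estimated correlation for each). Without the 4 libraries with a falling GC slope the median turned to 0.0075. Ribosomal protein genes were below 0 in 51 of 75 (median -0.12), with Rpl30 at -0.46 (SE 0.11) and Rpl23a at -0.50 (SE 0.13). Mitosis genes were below 0 in 27 of 32 (median -0.18), with Hmmr at -0.60 (SE 0.22). Heat shock genes, a list of cytosolic chaperones that also holds the mitochondrial pair Hspd1 and Hspe1, were below 0 in 15 of 18 (median -0.18), with Hspe1 at -0.41 (SE 0.11) and the cytosolic Hsp90aa1 at -0.38 (SE 0.13). Axon guidance genes were above 0 in 16 of 18 (median 0.34), with Plxna1 at 0.43 (SE 0.12) and Unc5b at 0.48 (SE 0.17). With the trend on GC content and transcript length removed their median was 0.073 (camera adjusted p = 0.738). With GDNF replicate 3 left out as well it was -0.0052 (0.769).

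Glycolysis genes were above 0 in the interaction in 18 of 23 members (median 0.13), with Slc2a1 at 0.39 (SE 0.13). Without the 4 libraries with a falling GC slope the glycolysis group was called in the other direction (median -0.058, adjusted p = 0.0447), with 1 library left in each group given 1 agent alone, and with the trend on GC content and transcript length removed and GDNF replicate 3 left out its median was -0.015. Genes of the ATF4 amino acid response were above 0 in 21 of 31 (median 0.14), with the amino acid transporter Slc7a5 at 0.47 (SE 0.15) and the serine pathway enzyme Shmt2 at 0.43 (SE 0.15). NF-kB and inflammatory genes were above 0 in 13 of 16 (median 0.27), with the NF-kB inhibitor Nfkbia at 0.63 (SE 0.24). ERK-induced genes were above 0 in 22 of 29 (median 0.19), with Fosl2 at 0.38 (SE 0.15) and Ier2 at 0.49 (SE 0.24). GDNF replicate 3 stood farthest from the control mean of the 12 libraries for mitosis, heat shock, axon guidance, glycolysis, ATF4, NF-kB and ERK genes and for the mitochondrial genes, at 0.29, 0.17, -0.43, -0.38, -0.26, -0.41, -0.20 and 1.15.

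In edgeR 0 genes passed for the interaction (smallest adjusted p = 0.240, 1900 at an unadjusted p under 0.05), in DESeq2 0 (smallest adjusted p = 0.0724, 1650 unadjusted) and in limma-voom 0 (1960). In edgeR 403 passed with no filter and 21 with the trend on GC content and transcript length removed and GDNF replicate 3 left out. With sample quality weights limma-voom passed 2425. The genes with the smallest p did not pass. Among them were Crocc at 0.85 (SE 0.17), Mfsd3 at 1.80 (SE 0.37), Rpl36a at -0.60 (SE 0.13), Snrpd1 at -0.70 (SE 0.16) and Ube2v2 at -0.59 (SE 0.14). Adjusted over the list alone, 18 of 75 ribosomal, 8 of 12 mitochondrial and 2 of 18 heat shock genes passed, all below 0, with 0 members of the other 6 groups and 0 over all genes. The 9 camera calls had adjusted p = 0.000120 to 0.0424. Without GDNF replicate 1, which leaves only GDNF replicates 2 and 3 with their falling GC slopes, 1887 genes passed in edgeR. Without GDNF replicate 3, 14 passed, 8 above 0 and 6 below. Without GDNF replicate 3 the glycolysis (adjusted p = 0.0949) and NF-kB (0.104) calls ended. The NF-kB call also ended without control replicate 1 or 3, GDNF replicate 1, anti-NCAM1 replicate 3, or GDNF plus anti-NCAM1 replicate 1 or 3 (0.0516 to 0.101). The ERK call ended without control replicate 1 or 3, GDNF replicate 1 or 2, anti-NCAM1 replicate 3, or GDNF plus anti-NCAM1 replicate 2 or 3 (0.0506 to 0.0778), and the ATF4 call without control replicate 3 (0.0740) or GDNF plus anti-NCAM1 replicate 1 (0.0516). The other 5 calls held without each of the 12 libraries, though not their sizes.

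Medians of 8 of the 9 groups in the interaction, in limma-voom values, moved by over 1.5 times without single libraries. On omitting GDNF replicate 3, the mitochondrial genes went from -0.75 to -0.41, mitosis from -0.17 to -0.086, heat shock genes from -0.17 to -0.071, axon guidance from 0.35 to 0.21, glycolysis from 0.14 to 0.061, ATF4 genes from 0.20 to 0.086 and NF-kB genes from 0.29 to 0.19. NF-kB genes stood at 0.18 without anti-NCAM1 replicate 3, and glycolysis at 0.22 without GDNF replicate 1. Ribosomal proteins went from -0.11 to -0.070 without control replicate 2 and -0.072 without GDNF replicate 2. Removal of the trend on GC content and transcript length kept the calls of ribosomal (-0.12, adjusted p = 0.00156), heat shock (-0.13, 0.00943) and mitosis genes (-0.13, 0.0357) and ended the other 6. When GDNF replicate 3 was left out too, the ribosomal call stayed (-0.12, 3.53e-17), and those of heat shock (-0.080, 0.105) and mitosis genes (-0.038, 0.439) ended.

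Across the 11332 genes, the log2 effect of GDNF without the antibody and its effect with the antibody had a Pearson correlation of -0.24 and a Spearman correlation of -0.34 (permutation p = 0.13 for the former, 400 relabellings within arms). The effect of the antibody without GDNF and with GDNF had a Pearson correlation of -0.28 and a Spearman correlation of -0.36 (permutation p = 0.13). These are the 2 correlations computed, each between effects that share no library, and the p adjusted over both is 0.13. They are across genes, which are not independent replicates. Without anti-NCAM1 replicate 2 they were -0.32 (permutation p = 0.01, 200 relabellings) and -0.35 (p = 0.04), and without GDNF replicate 1 the second was -0.33 (p = 0.03). The first was -0.16 without anti-NCAM1 replicate 1 and -0.14 without anti-NCAM1 replicate 3, and the second was -0.18 without GDNF replicate 3. With the trend on GC content and transcript length removed both were -0.08 (permutation p = 0.11 and 0.12), and without the 4 libraries with a falling GC slope they were 1.56e-05 and 0.02 (16 relabellings).

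GDNF and the antibody were also compared with each other, the contrast in the title of the series. Mitochondrially encoded genes were higher with GDNF in 10 of 12 members (median 0.54, camera adjusted p = 0.00135, n = 3 against 3), with mt-Nd2 at 0.78 (SE 0.26). This call, like those of the 4 groups that follow, was lost when the correlation between genes was estimated (adjusted p = 0.767 with an estimated correlation for each). Mitosis genes were higher in 26 of 32 (median 0.13), with Kif20a at 0.21 (SE 0.10). Glycolysis genes were lower with GDNF in 21 of 23 (median -0.09), with Pfkfb4 at -0.30 (SE 0.18), antigen presentation genes in 10 of 12 (median -0.21), with Psmb8 at -0.33 (SE 0.15), and ribosomal protein genes in 49 of 75 (median -0.06), with Rps13 at -0.21 (SE 0.08). GDNF replicate 3 was the library farthest from control in the first 4 of these groups, and its ribosomal level of -0.08 was below the 11 others. The glycolysis median turned to 0.0055 with the trend on GC content and transcript length removed and GDNF replicate 3 left out, the mitosis median to -0.027 without the 4 libraries with a falling GC slope, and the ribosomal median to 0.0091 with sample quality weights.

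For GDNF against the antibody, the single genes with the smallest p were Mir17hg, the host transcript of a microRNA cluster, at 1.02 (SE 0.20), Rbm39 at 0.34 (SE 0.09), the translation factor Eif4a2 at 0.33 (SE 0.09), Tmem54 at -1.95 (SE 0.50), Ebpl at -0.73 (SE 0.20) and Armt1 at -0.36 (SE 0.10). In edgeR 0 genes passed (smallest adjusted p = 0.705, 717 at an unadjusted p under 0.05), in limma-voom 0 (729), and in DESeq2 1, Mir17hg (adjusted p = 0.0464, 549 unadjusted). In edgeR 83 passed with no filter and 2 with the trend on GC content and transcript length removed and GDNF replicate 3 left out. With sample quality weights limma-voom passed 2. Adjusted over the list alone, 8 of 12 mitochondrial genes passed, 7 higher and 1 lower, and 0 members of the other 4 groups, against 0 over all genes. The 5 camera calls had adjusted p = 0.00135 to 0.0493. Without GDNF replicate 3, 0 groups were called, with adjusted p = 0.121 for mitochondrial, 0.611 for antigen presentation, 0.807 for ribosomal, 0.822 for mitosis and 0.895 for glycolysis genes. The antigen presentation (0.0829) and glycolysis (0.0939) calls also ended without anti-NCAM1 replicate 2, and the ribosomal call without any of the 3 control libraries, the 3 libraries given both agents, GDNF replicate 1 or anti-NCAM1 replicate 3 (0.0514 to 0.612). Without GDNF replicate 1, which leaves only GDNF replicates 2 and 3 with their falling GC slopes, 126 genes passed in edgeR, 89 higher and 37 lower.

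Medians of the 5 groups for GDNF against the antibody, in limma-voom values, moved by over 1.5 times without single libraries. In the 11 libraries other than GDNF replicate 3, the mitochondrial genes went from 0.46 to 0.12, mitosis from 0.12 to 0.0012, glycolysis from -0.11 to 0.0045, antigen presentation from -0.24 to -0.049 and ribosomal proteins from -0.067 to -0.0018. When GDNF replicate 1 was omitted the first 4 stood at 0.71, 0.21, -0.21 and -0.36. Mitosis stood at 0.078 without anti-NCAM1 replicate 2, and ribosomal proteins at -0.11 without GDNF replicate 2 and -0.031 without anti-NCAM1 replicate 3. Removal of the trend on GC content and transcript length kept the calls of mitochondrial (0.37, adjusted p = 0.0310), mitosis (0.060, 0.0310) and antigen presentation genes (-0.16, 0.0310) and ended those of glycolysis (-0.066, 0.109) and ribosomal genes (-0.045, 0.109). With GDNF replicate 3 left out as well, mitochondrial genes stayed called (0.094, 0.0347) and the other 4 did not.

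Cells given both agents were compared with control last, a pair of groups whose GC slopes were all above 0 but did not overlap (0.08 to 0.12 in control, 0.05 to 0.07 with both). Ribosomal protein genes were above control in 68 of 75 members (median 0.05, camera adjusted p = 0.00185, n = 3 against 3), with Rpl21 at 0.14 (SE 0.08) and Rps23 at 0.10 (SE 0.06). This call and the next were lost when the correlation between genes was estimated (adjusted p = 0.781 with an estimated correlation). The 7 tested of 23 epithelial markers were above control in 5 (median 0.25, adjusted p = 0.0322), with the epithelial transcription factor Elf3 at 1.16 (SE 0.44) and Krt8 at 0.09 (SE 0.07). The level of the group was 0.23 to 0.29 in the 3 libraries. Elf3 had only 4 to 17 counts per library, at 0.910 CPM in control and 2.13 with both. Epcam stood at 13.6 CPM in control and 13.5 with both, and Ovol1 at 2.32 and 2.16. Genes with small p that did not pass include Krt16 at 1.49 (SE 0.43), Cfap69 at 0.63 (SE 0.19), Sipa1l1 at -0.27 (SE 0.08), the clock gene Per1 at -0.39 (SE 0.12) and Dffb at -0.92 (SE 0.28). In edgeR 0 genes passed (smallest adjusted p = 1.00, 221 at an unadjusted p under 0.05), in DESeq2 0 (114) and in limma-voom 0 (212). In edgeR 24 passed with only the compared groups fitted, 4 with no filter and 24 without the 4 libraries with a falling GC slope, and limma-voom with sample quality weights passed 0. Adjusted over the list alone, 0 members of either group passed, and 0 over all genes. Without control replicate 1 both ended (adjusted p = 0.122 for ribosomal and 0.0925 for epithelial genes), as they did without control replicate 2 (0.0531 and 0.0971), leaving 0 groups. The epithelial call also ended without GDNF plus anti-NCAM1 replicate 1 (0.0896), leaving 1, and 4 groups were called without GDNF replicate 1, GDNF replicate 3 or anti-NCAM1 replicate 2. Without control replicate 3 the medians in limma-voom values went from 0.046 to 0.076 for ribosomal proteins and from 0.25 to 0.12 for epithelial markers. After removal of the trend the ribosomal call ended (0.019, adjusted p = 0.648) and the epithelial call stayed (0.25, 0.0167). When GDNF replicate 3 was left out too, both were called (0.018, 0.0204 and 0.25, 0.00873).

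The 95% intervals of the log2 fold changes lay within 2-fold either way for 90.1% of genes for GDNF against control, 91.8% for the antibody against control and 78.7% for the interaction. In counts simulated at these depths for GDNF against control, with genes varying independently and no library standing apart, the edgeR test recovered 56.7% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 89.4% of those changed 3-fold.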

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

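The tests of what sets GDNF replicate 3 and 3 other libraries apart, and of what the interaction calls rest on, were chosen only after those results were seen; the counts of other splits of the samples were chosen before.

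In the test of the difference between the effect of GDNF with and without the antibody, camera called 9 gene groups. Their median differences on the log2 scale were -0.84 for mitochondrially encoded genes, -0.12 for ribosomal proteins, -0.18 for mitosis, -0.18 for heat shock proteins, 0.34 for axon guidance, 0.13 for glycolysis and glucose uptake, 0.14 for the ATF4 amino acid response, 0.27 for NF-kB and inflammatory genes and 0.19 for ERK-responsive genes. With an estimated correlation between genes, 0 of the 9 were called (adjusted p = 0.507). Of 100 splits of the 12 samples, 3 called as many groups as the real one, which called 9; the highest of the others called 10, and 77 of them called at least 1. The share of 3 in 100, with the real split among the 100, is under 0.05. These splits move all 12 libraries between all groups, so effects of single agents and libraries that stand apart count too. They do not test the interaction alone, and a grouping by chance is not excluded. No gene passed in edgeR in the real split or in the others (0 against 0), so 100 of 100 splits had as many. With a real count of 0 that share was fixed in advance and decides nothing.

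The interaction calls were fitted again in 3 ways, with medians given here in the limma-voom values on which camera runs, which differ from the edgeR medians above. After removal of the GC content and transcript length trend, 3 of the 9 stayed: ribosomal proteins went from -0.11 to -0.12 (adjusted p = 0.00156), mitosis from -0.17 to -0.13 (0.0357) and heat shock proteins from -0.17 to -0.13 (0.00943). At the preset correlation these 3 calls thus do not rest on the fitted trend alone. Camera there does not directly measure the spread between cultures. Other splits of the samples, with the trend in place, called a median of 3 groups. What remains of these 3 is therefore not decided by this refit. With GDNF replicate 3 left out as well, ribosomal proteins stayed (-0.12, adjusted p = 3.53e-17), while heat shock proteins (-0.080, 0.105) and mitosis (-0.038, 0.439) ended, so the trend and that library together stay open as the cause of the latter pair. The other 6 shrank to 0.253 of their size (median), so the trend may account for much of them, and mitochondrially encoded genes went from -0.75 to -0.35 (adjusted p = 0.0710).

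Without GDNF replicate 3, 7 of the 9 interaction calls stayed at the preset correlation, so these 7 do not rest on that library alone. That library may still be a large part of their source, and what remains of them is not decided by this refit. Of these 7, mitochondrially encoded genes went from -0.75 to -0.41, mitosis from -0.17 to -0.086, heat shock proteins from -0.17 to -0.071, the ATF4 response from 0.20 to 0.086 and axon guidance from 0.35 to 0.21, while ERK-responsive genes stood at 0.18 and ribosomal proteins at -0.16. Of the 2 that ended, glycolysis went from 0.14 to 0.061 and NF-kB from 0.29 to 0.19, together 0.578 of their size; 1 fell below the share of 0.5 set for that library as the cause and 1 did not, so it stays open. Without the 4 libraries with a falling GC trend, 1 stayed, ribosomal proteins at -0.16, and the other 8 shrank to 0.187 of their size. The groups given 1 agent alone then hold 1 library each and their spread is assumed from the other groups, so this refit decides nothing about the cause.

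GDNF replicate 3 stood at 44.1 on the first principal component of the 12 libraries, which held 33.5% of the variance. After removal of the GC content and transcript length trend it stood at 38.6 and the others at -0.626 or below, so that trend is argued against as the whole cause. The highest of 3 sums of markers of leukocytes, endothelium or neurons and glia lay 0.373 SD above the mean of the other 11 libraries. This is the endothelial sum, of which Eng makes up 89.5%, a baseline that would hide a small share, so it decides nothing; the other 2 sums were lower than in any of the 11. The other 5 libraries given GDNF had a median score of -6.33, but scores are centred, so 1 library far above 0 puts the others below it and this decides nothing. All 5 lay above the highest control (-7.47), with GDNF replicate 2 at 7.38, but so did anti-NCAM1 replicates 1 and 3, given no GDNF, at 3.31 and 3.32. GDNF replicates 1 and 2, given the same treatment, stood at -6.97 and 7.38, against 44.1 for GDNF replicate 3. This argues against GDNF as the whole cause for replicate 3. A part played by GDNF stays open, as do RNA quality and library preparation, which were not tested.

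GDNF replicate 2 and anti-NCAM1 replicates 1 and 3 stood at -15.8, -9.84 and -13.3 on the second component (10.0% of the variance). The lowest GC slope of the other 4 libraries given the antibody was 0.0492. The slope is what set the 3 apart, so this decides nothing about an effect of the antibody. GDNF replicate 2 was given none, so the antibody is not what all 3 share. An effect of it on anti-NCAM1 replicates 1 and 3 stays open. After removal of the trend the nearest of the 3 scores was -7.14, still apart from the other libraries, which argues against the trend as the whole cause. What the 3 share beyond it was not tested.

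With 3 samples against 3 there are 10 splits, the real one included, too few for a share under 0.05. Each number of splits with as many or more given here also counts the real one. For genes passing in edgeR, the 6 comparisons of a pair of groups each had 10 of 10 splits with as many (real 0, highest other 0). With a real count of 0 this was fixed in advance and decides nothing. For gene groups called, GDNF against control had 2 splits with as many (real 7, highest other 7, where control replicate 2 was placed with GDNF replicates 2 and 3), and the antibody against control had 1 (real 6, highest other 3). GDNF plus antibody against GDNF had 4 (real 5, highest other 7), and against the antibody 4 (real 1, highest other 2). GDNF against the antibody had 5 (real 5, highest other 8), and GDNF plus antibody against control had 2 (real 2, highest other 2).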

How the results depend on the processing

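The removal of the trend (alone or without GDNF replicate 3), the data without 4 libraries, the quality weights, the filter of 5 CPM and DESeq2 without independent filtering were chosen only after the results were seen.

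Counts of genes are given in the order GDNF against control, antibody against control, GDNF plus antibody against GDNF, GDNF plus antibody against antibody, interaction, GDNF against antibody, GDNF plus antibody against control. In edgeR they were 0 in all 7. They were also 0 in all 7 with limma-voom, DESeq2 size factors, upper-quartile scaling, filters of 1 or 5 CPM and robust estimation. The same held with the replicate number as a block and with removal of the trend. An added 1.5-fold threshold also gave 0, but it can only remove calls, so this was fixed in advance. DESeq2 gave 31, 0, 0, 0, 0, 1, 0, and without independent filtering 0, 0, 0, 0, 0, 1, 0: the 31 came from adjusting over 1885 genes. With no filter they were 736, 8, 348, 4, 403, 83, 4 over 22404 genes, where the prior degrees of freedom went from 8.73 to infinity. With only the compared groups fitted, 33 passed for antibody against control, 5 for GDNF plus antibody against antibody, 24 for GDNF plus antibody against control and 0 for the other 3. With limma-voom and sample quality weights, they were 2614, 277, 1462, 7, 2425, 2, 0. With the trend removed and GDNF replicate 3 left out, they were 1 (Naca), 18, 1 (Eif4a2), 0, 21, 2 (Eif4a2 and Mir17hg), 0. Without the 4 libraries with a falling GC trend, they were 1 (Mt2), 38, 4 (Eif4a2, mt-Rnr2, Nfat5 and Wsb1), 9, 16, 13, 24, where the groups given 1 agent alone had 1 library each. Genes named here that the naming rule does not hold were chosen after their values were seen. Beyond the fewer libraries and the prior, the cause was not tested.

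Leaving out each library in turn gave, lowest to highest in the same order, 0 to 2714, 0 to 8, 0 to 1990, 0 to 0, 0 to 1887, 0 to 126 and 0 to 0 genes. All the highest values above 0 came without GDNF replicate 1 except the 8, which came without GDNF replicate 3. Without GDNF replicate 1 the GDNF group holds only replicates 2 and 3, both with falling GC slopes. The interaction also had 14 without GDNF replicate 3. Groups called ranged 4 to 8, 3 to 11, 2 to 7, 1 to 7, 6 to 11, 0 to 6 and 0 to 4. The correlations between arms ranged from -0.32 to -0.14 for the GDNF effect and -0.35 to -0.18 for the antibody effect. After removal of the trend both were -0.08, and without the 4 libraries they were 1.56e-05 and 0.02.

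Gene groups called by camera were 7, 6, 5, 1, 9, 5, 2, and 0, 0, 0, 0, 0, 0, 0 both with an estimated correlation and by fry. DESeq2 size factors gave 4 for GDNF plus antibody against control. The replicate block gave 10 for antibody against control. The filter of 5 CPM gave 3 for antibody against control, 3 for GDNF plus antibody against antibody and 1 for GDNF plus antibody against control. Removal of the trend gave 2 for antibody against control, 3 for the interaction, 3 for GDNF against antibody and 1 for GDNF plus antibody against control. With the trend removed and GDNF replicate 3 left out there were 1 for GDNF against control, 2 for GDNF plus antibody against GDNF, 1 for the interaction and 1 for GDNF against antibody. Without the 4 libraries there were 3 for GDNF against control, 1 for GDNF plus antibody against GDNF, 3 for GDNF plus antibody against antibody, 4 for the interaction, 2 for GDNF against antibody and 7 for GDNF plus antibody against control. Quality weights gave 7 for GDNF plus antibody against antibody, 1 for GDNF against antibody and 4 for GDNF plus antibody against control. Of 35 calls, DESeq2 size factors and the filter of 1 CPM kept 35, the block 34, the filter of 5 CPM 30, quality weights 27, removal of the trend 16, the 4 libraries left out 12, and removal without GDNF replicate 3 kept 10. The cause was not tested further.

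Called groups whose direction by camera reversed are given with their medians. With the trend removed they were matrix genes for GDNF against control (0.025) and axon guidance for GDNF plus antibody against GDNF (-0.020). With the trend removed and GDNF replicate 3 left out, they were glycolysis and axon guidance for GDNF plus antibody against GDNF (-0.0021 and -0.031), glycolysis in the interaction (-0.015) and for GDNF against antibody (0.0055). Without the 4 libraries they were glycolysis and antigen presentation for GDNF against control (0.0075 and 0.030), glycolysis, mitosis, antigen presentation and axon guidance for GDNF plus antibody against GDNF (-0.030, 0.011, -0.024 and -0.094), glycolysis (-0.058, called in the other direction at adjusted p = 0.0447) and mitochondrially encoded genes (0.0075) in the interaction, and mitosis for GDNF against antibody (-0.027). With quality weights it was ribosomal proteins for GDNF against antibody (0.0091). Other medians crossed 0 while camera kept the direction. Among them, with the trend removed and GDNF replicate 3 left out, were axon guidance in the interaction (-0.0052) and glycolysis for GDNF against control (0.00010). Oxidative phosphorylation for antibody against control was another in that setting (-0.00048). Without GDNF replicate 3 alone it was glycolysis for GDNF against antibody (0.0045). The cause was not tested.

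Of 203 results of named genes, 127 passed under at least 1 alternative, 109 of them with quality weights, 102 without GDNF replicate 1 and 70 with no filter, with overlap; 91 values changed sign with no call on either side. Of 585 values for Ncam1, Gdnf and Fyn, 2 passed, both for Gdnf with quality weights: -0.42 for GDNF against control (adjusted p = 0.0311) and 0.67 in the interaction (adjusted p = 0.0200).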

Other observations

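Between groups, the correlation across genes of the deviations of libraries with the same replicate number ran from -0.147 to 0.101 over 18 pairs. In 8 of the 18 pairs the library with the same number was the closest of the 3 in the other group, and 1 pair was over 0.1. The numbers were not used to pair cultures except in the alternative with the replicate number as a block.

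Markers of other cell types were at these levels: Eng 68.1 CPM, Tubb3 38.9, Col1a1 306 and Cd68 6.66 on average, and Ptprc had 0 to 1 counts per library. In GDNF replicate 3 the summed markers of endothelium stood at 79.4 CPM (75.8 ± 9.83 in the other 11, SD), of leukocytes at 9.21 (11.2 ± 1.07) and of neurons and glia at 33.6 (52.8 ± 4.50).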
